A study of Pseudoalteromonas sp. GCY with 6 samples.

How the data were processed

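Transcript levels of Pseudoalteromonas sp. GCY, a marine bacterium from sediment, were measured by Illumina RNA sequencing in 6 samples. The labels place 3 samples in a group treated for 27 h with IBP, an abbreviation that they do not spell out, and 3 in an untreated control group. No hours are listed for the controls, so whether they were sampled at the same time is not known. The titles of all samples, controls included, begin with IBP, and the group is given in brackets. RNA was extracted with Trizol and libraries were made with a TruSeq RNA kit, per the labels' protocols. Nothing in the labels says whether replicates came from separate cultures, or names a batch, a day or a pairing.

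One table of the whole series was used. It lists 4876 rows, of which 4693 are mRNA genes and 183 are sRNA candidates, with a gene name and product for the annotated genes, and it holds no read counts. The 3 control columns are treated here as TPM (a length-corrected share of each sample's transcripts) deposited by the authors, because their totals of 997980 to 998428 are nearly equal and are those that TPM over nearly all transcripts would give. The unit is not named in the table. The 3 treated columns are a deposited signal whose unit is also not named, and they sum to 1338111 to 1540663, so they are not on the TPM scale of the controls. The authors also deposited a fold change (a linear ratio of treated over control), its log2 value, a p-value and an adjusted p-value per row. The test behind these p-values is not given in the sources used here. Bowtie2 2.2.3, HTSeq 0.6.1, DESeq 1.18.0, edgeR, Picard 1.96, SAMtools 0.1.18 and GATK are named in the submitters' processing notes, without a role or an order. The same notes name mm8, a mouse genome build, so the reference genome used for this bacterium is not given in the sources used here. Genes are therefore identified by the locus numbers and names of the table, without coordinates. A number at the end of a name (katG_1, katG_2) marks rows that share a gene name, and how reads shared between such copies were counted is not given in the sources used here. TPM keeps no sequencing depth, so depth is unknown, and no counting interval is given.

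Before any test was run, the columns were compared with each other. In every row, the deposited fold change was multiplied by the control value of the same replicate number. The constant for each treated column was the median of treated value over this product, rounded to 2 decimals. The authors' treated mean was then compared with the product at a relative tolerance of 1e-09, and single cells at the rounding of the columns, 0.005. On simulated independent libraries, with the controls' own spread, 0 of 4841 rows matched. With treated columns made as products, 4841 of 4841 did. Rounded values with noise cannot meet this tolerance and unrounded products always do. Both outcomes were thus fixed in advance and check only that the calculation works. Libraries paired by replicate number were not simulated.

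The plan made before the data were examined was a test of 3 treated against 3 control samples with limma on log2(value + 1), since there are no counts, with camera and fry for the gene lists. These tests were not run. The treated columns restate the control columns (see the results), so they hold no spread between treated samples of their own, and a p-value from them would not measure the response. The correlation of deviations from the group mean, across the 2857 genes at 10 or more in all 6 columns, was 1 for replicate number 1, 0.9984 for number 2 and 0.9985 for number 3. By this check the numbers pair the columns, but through the product and not through a shared origin that the labels state. Errors are given for the control group only, as SD over 3 samples. The control columns were not searched for values repeated across genes, and some do repeat (see the results). All fold changes, p-values and calls are those of the authors' deposited table, with no error of their own. A gene is called where the deposited adjusted p is under 0.05.

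Gene lists (33, from bacterial physiology) were fixed before the data were examined, by gene symbol or product text. The 30 with at least 5 annotated members above 0 in a control column were used; the TonB, type IV pili and extracellular peptidase lists had fewer. For each list, called members were counted over all rows and again with Benjamini-Hochberg adjustment of the deposited p-values over the list alone. The second count reuses the same p-values over far fewer rows, and in no list was it below the first. It is therefore not separate support for the calls. The median deposited log2 fold change was placed among the medians of 10000 random lists of the same size, matched in 10 bins of control TPM. This percentile describes the table and is not a test across samples. On simulated lists of 30 genes, 200 of 200 lists shifted by 1 log2 unit passed the 95th percentile, as did 11 of 200 unshifted lists. Lists as small as the smallest used (6 genes), and shifts as small as the observed medians (0.84 at most), were not simulated. The percentiles were not adjusted for the number of lists. The named genes are, by a rule fixed in advance, the 8 higher and 8 lower called genes with the largest fold among those with a mean level of 10 or more, non-overlapping groups and a product name, the 4 of each direction with the highest mean over all 6 columns, up to 2 called members per list by p, and called neighbours of the first set. The mean level and the overlap of groups in this rule include the treated columns, which are not measurements of their own, so a large fold raises a gene's place, and the higher genes taken by mean are not those with the highest control TPM. The part of the rule that needed camera was not used. The 3 added sulfur genes and the other genes named outside this rule were chosen after their values were seen.

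Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 was used. All per-sample columns of the table were assigned to samples.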

Results

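The table held transcript levels of 4876 rows in 3 control samples and 3 samples treated with IBP for 27 h. The question set by the labels is which genes differed in level after this treatment. The control columns summed to 997980, 998126 and 998428. Across genes, the Pearson correlation of log2(TPM + 1) was 0.9782 for controls 1 and 2, 0.9772 for controls 1 and 3, and 0.9799 for controls 2 and 3. One row, lepA (elongation factor 4, locus 03576), took 22.7% of the control total, and the 10 most abundant rows took 46.5%. Some control values repeat across genes. The ribosomal protein gene rpsO, the chemotaxis gene mcpU and a mobile element gene without a symbol share a control level of 134.367 ± 62.0552 TPM. Their folds in the authors' deposited table are 2.689, 0.5012 and 0.9026. How many rows share control values was not counted, so control levels and their SDs are open to doubt to that extent.

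The treated columns were not independent measurements of these genes. In 4790 of the 4841 rows with a treated mean above 0 (98.9%), that mean equalled the authors' fold change times the control values, weighted by one constant per column, within a relative difference of 1e-09. The constants were 1 for IBP replicate 1, 1.05 for replicate 2 and 0.92 for replicate 3, each multiplying the control of the same number. Of the other 51 rows, 49 equalled control times fold change with the constant 1 in all 3 columns, and all 49 were among the 51 rows with a fold above 7. The remaining 2 rows were cysD and cysJ, genes of sulfate assimilation. Their treated values over control times fold change were below 1 for replicates 1 and 2 and above 1 for replicate 3. These ratios were nearly the same in both rows, so cysD and cysJ cannot be taken as independent measurements either. Between controls 2 and 1, the log2 ratio had an SD of 0.308 over genes, and between IBP 2 and IBP 1 it had an SD of 0.308. The difference of these ratios had an SD of 0.00818 over the same 2857 genes, those at 10 or more in all 6 columns. The treated columns therefore add no replicate error, and no difference between the groups could be held against a spread between treated samples. A further 35 rows were at 0 in all 6 columns and still had a fold change, beyond 2-fold in 12 of them.

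**Figure D1:**
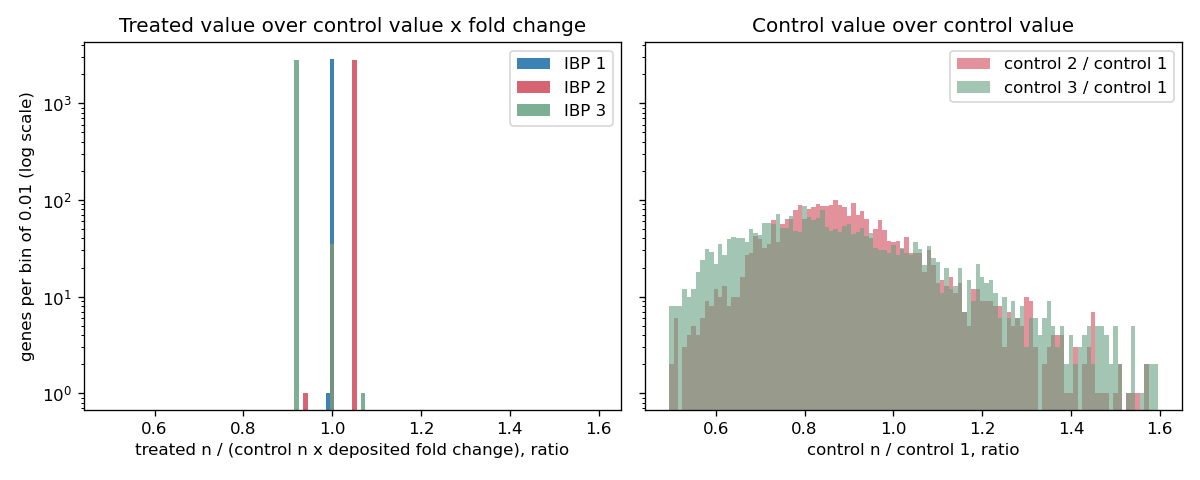
Left, each treated value divided by the control value of the same number times the deposited fold change, for the 2857 genes at 10 or more in all 6 columns; right, controls 2 and 3 divided by control 1, shown from 0.5 to 1.6. Both vertical axes count genes per bin on a log scale, and the treated ratios fall in narrow spikes at 1, 1.05 and 0.92, while the control ratios spread broadly.

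The authors' deposited table calls 149 rows at an adjusted p under 0.05, of which 102 are listed as higher and 47 as lower after IBP. By type, 145 are mRNA genes and 4 are sRNA candidates, and 52 of the called genes have only a hypothetical product. A fold of at least 2 is listed for 146 of them, 99 higher and 47 lower. At an adjusted p under 0.01, 89 calls are left. Among those no longer called are hsp90, fliD, copA_1, sdhC, yhaH, mntP, bioH, cysJ, cysC, cysH, cysI, recF, recN, sRNA0135, sRNA0187 and the gene at locus 00069. The median log2 fold change over all rows is 0.16. Of the called rows, 23 are among the 49 with one constant in all treated columns.

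All 6 subunits of the Na(+)-translocating NADH-quinone reductase, a respiratory enzyme that exports sodium, are called higher in the authors' deposited table. The genes nqrF to nqrA have the consecutive locus numbers 00901 to 00906. In the controls, nqrD was at 34.7 ± 3.58 TPM (SD, n = 3), nqrF at 52.2 ± 4.15 TPM, nqrC at 39.4 ± 5.84 TPM and nqrE at 7.91 ± 2.25 TPM. Listed log2 fold changes in the authors' deposited table are 8.23 for nqrD (300.0-fold), 6.34 for nqrF (81.1-fold), 5.36 for nqrE (41.1-fold) and 5.04 for nqrC. Of the 24 genes of the respiratory chain and ATP synthase list, 7 are called higher, 0 lower and 17 not, and 7 are called when adjusted over the list alone. No member has an ATP synthase gene symbol, so these counts do not cover that enzyme. The list also took in ahpF, which is in the oxidative stress list as well. The list's median log2 fold change is 0.34, at percentile 81.5 of random lists. Without the rows of constant 1, which hold all 6 nqr genes, 1 call is left in this list.

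Genes of fatty acid breakdown are also listed as higher. The thiolase gene fadI was at 21.3 ± 2.49 TPM in the controls and its neighbour fadJ, the alpha subunit of the beta-oxidation complex, at 69.3 ± 12.1 TPM. Their folds in the authors' deposited table are 288 and 75.6. In the beta-oxidation list, 3 of 18 members are called higher, 0 lower and 15 not (3 adjusted over the list alone). Its median log2 fold change of 0.82 lies at percentile 99.9 of random lists. Both fad genes are rows of constant 1, and 1 call is left without such rows. The fatty acid synthesis list has 2 of 28 members called higher and 1 lower (3 adjusted over the list alone), and 1 of these 3 is a gene of that pathway: fabZ_1, a dehydratase of chain elongation, at 454 ± 21.8 TPM in the controls and a fold of 4.01 in the authors' deposited table. The other 2 matched on the acyl carrier protein in their product names. They are lpxA, the lower call and the first acyltransferase of lipid A synthesis, at 73.2 ± 23.2 TPM and a fold of 0.297 in the authors' deposited table, and bioH, a gene of biotin synthesis named after its value was seen, at 37.6 ± 4.78 TPM and a fold of 2.83.

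Of 23 oxidative stress genes, 3 are called higher and 0 lower, with 20 not called, while the list's median log2 fold change is -0.09, at percentile 9.4. Adjusted over the list alone 4 are called, and the added gene is listed as lower: tpx, a thiol peroxidase gene named after its value was seen, with a log2 fold change of -1.64 in the authors' deposited table. The catalase-peroxidase genes katG_1 and katG_2, whose products break down hydrogen peroxide, were at 198 ± 45.6 and 10.6 ± 0.166 TPM in the controls. Their folds in the authors' deposited table are 74.2 and 12.3, and both are rows of constant 1, without which 1 call is left. Among 33 chaperone and heat shock protease genes, 3 are called higher, 0 lower and 30 not, with a median of 0.06 at percentile 27.4. Adjusted over the list alone 4 are called, the added gene being ibpA_1, a small heat shock protein gene named after its value was seen, listed as lower at -1.62 log2 units in the authors' deposited table. Called members include hsp70 and hsp90, chaperone genes with folds of 5.67 and 5.39 in the authors' deposited table. Control levels were 9.54 ± 0.826 TPM for hsp70 and 74.6 ± 25.4 TPM for hsp90. In the DNA repair list, 4 of 38 genes are called higher and 0 lower (4 adjusted over the list alone), and 2 are left at an adjusted p under 0.01. The mismatch repair gene mutH and repair gene radA are listed at folds of 3.30 and 5.92 in the authors' deposited table, from 10.7 ± 2.14 and 39.1 ± 6.51 TPM.

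Of the 18 members of the list of sulfate assimilation and cysteine synthesis, 7 are called higher, 0 lower and 11 not (8 called adjusted over the list alone). These are matches by symbol or product text, and not every member need belong to that pathway. Among those not called are cysS and metXA, which are in the synthetase and amino acid biosynthesis lists as well. At an adjusted p under 0.01, 2 calls are left. The list's median log2 fold change is 0.53, at percentile 95.6. The sulfate adenylyltransferase gene cysN and the nucleotidase gene cysQ_1 were at 16.8 ± 6.48 and 9.90 ± 1.72 TPM in the controls and have folds of 2.51 and 2.67 in the authors' deposited table. The largest fold among the calls is that of cysI, a row of constant 1, at 28.8 there from 229 ± 27.9 TPM. The gene added over the list alone is cysL_1, listed as higher at 2.75 log2 units. Both cysI and cysL_1 were named after their values were seen. The list also holds the only 3 calls under 2-fold of the whole table. These are cysJ, cysC and cysH, with log2 fold changes of 0.15, 0.42 and 0.58 in the authors' deposited table, named after their values were seen. Their control levels were 17.0 ± 1.54, 18.5 ± 2.01 and 7.37 ± 1.06 TPM. Without the rows of constant 1 and the 2 rows that match neither product, 4 calls are left.

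Among the 58 genes of the multidrug efflux list, 4 are called higher, 1 lower and 53 not (5 called adjusted over the list alone), and the median of 0.08 lies at percentile 27.6. The transporter gene bmrA has a fold of 5.83 in the authors' deposited table, from 7.69 ± 2.22 TPM. Another efflux gene, abcA, lies next to fadI and has a log2 fold change of 2.32 in the authors' deposited table, from 352 ± 65.8 TPM. The list's product text also took in exporters of metals and amino acids. Among these are vacM, for nickel and cobalt efflux, at a fold of 4.78, and mntP, for manganese efflux and the 1 lower call, at 0.252, both from the authors' deposited table, with mntP named after its value was seen. Of 13 metal homeostasis genes, 1 is called higher and 1 lower (2 adjusted over the list alone): copA_1, a copper exporter, at a fold of 3.98, and cusB, a cation efflux protein, at 0.256, both from the authors' deposited table. Their control levels were 75.4 ± 12.7 and 181 ± 29.0 TPM.

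In central metabolism, 2 of 28 genes of sugar metabolism are called higher and 0 lower (2 adjusted over the list alone). The glycolytic gene eno, for enolase, was at 1310 ± 176 TPM and has a fold of 7.33 in the authors' deposited table. The other is aptA, for a subunit of apulose-4-phosphate transketolase, at 140 ± 13.8 TPM with a fold of 4.93. The member tktA is not called, at a fold of 0.837. The eno row has constant 1, and 1 call is left without such rows. In the tricarboxylic acid cycle list, sdhC is the 1 of 24 genes called (1 adjusted over the list alone), at a fold of 3.94 in the authors' deposited table from 2856 ± 289 TPM. The median log2 fold change of that list is 0.57, at percentile 98.7. The list also took in leuA and leuB (log2 fold changes of 0.899 and 0.565), which are in the amino acid biosynthesis list as well. Leucine dehydrogenase (ldh, 218 ± 27.9 TPM) and homogentisate 1,2-dioxygenase (hmgA, an enzyme of tyrosine breakdown, 189 ± 63.8 TPM) have folds of 40.8 and 25.1 in the authors' deposited table. Each is the 1 call of its list, of 7 branched-chain amino acid breakdown genes and of the 6 genes of the aromatic degradation list, both rows of constant 1. That second list also took in entA, of siderophore synthesis, and ubiA and ubiD, of ubiquinone synthesis, by their product names. Of the 93 members of the amino acid biosynthesis list, 0 are called, with deposited log2 fold changes between -1.62 and 2.66. These are matches by symbol or product text, and not every member need belong to that pathway. One of them, murE, is also in the list of cell division and peptidoglycan.

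Ribosomal protein genes include 3 of 54 called higher and 0 lower (3 adjusted over the list alone), with a median log2 fold change of 0.35 at percentile 94.6. Called members are rpsC, listed at 6.07-fold from 1.26 ± 0.195 TPM, and rplV, listed at 4.99-fold from 56.8 ± 26.9 TPM, in the authors' deposited table. The third is rplB, named after its value was seen, listed there at 4.37-fold from 0.907 ± 0.203 TPM. Both rpsC and rplB thus start from very low control levels. The control level of this list was low, with a median of 14.8 TPM against 21.1 TPM for all mRNA genes. Of 27 flagellar genes, 2 are called higher and 0 lower (2 adjusted over the list alone), fliD and fliS, at folds of 4.19 and 3.81 in the authors' deposited table from 24.7 ± 5.34 and 50.7 ± 12.7 TPM. Of 35 chemotaxis genes, 1 is called higher and 1 lower (2 adjusted over the list alone). These receptor genes are ctpL, at 3.08-fold from 30.1 ± 5.46 TPM, and mcpP_3, at 0.252-fold from 1220 ± 337 TPM, in the authors' deposited table. Mobile element genes have 2 of 68 members called higher and 0 lower (2 adjusted over the list alone), with a median of 0.42 at percentile 98.7. They are XerC, a recombinase gene with a fold of 7.27 in the authors' deposited table from 5.58 ± 0.949 TPM, and a transposase gene (locus 00741) with a fold of 3.83. The XerC row has constant 1, and 1 call is left without such rows. The mobile element list also took in fhuA_1 and fhuA_2, which are in the iron uptake list as well. The list meant for aminoacyl-tRNA synthetases has 31 members, of which 22 have such a product and 9 matched its symbol pattern only. Its 1 call, cysQ_1, is among these 9, so 0 of the 22 synthetase genes are called.

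**Figure D2:**
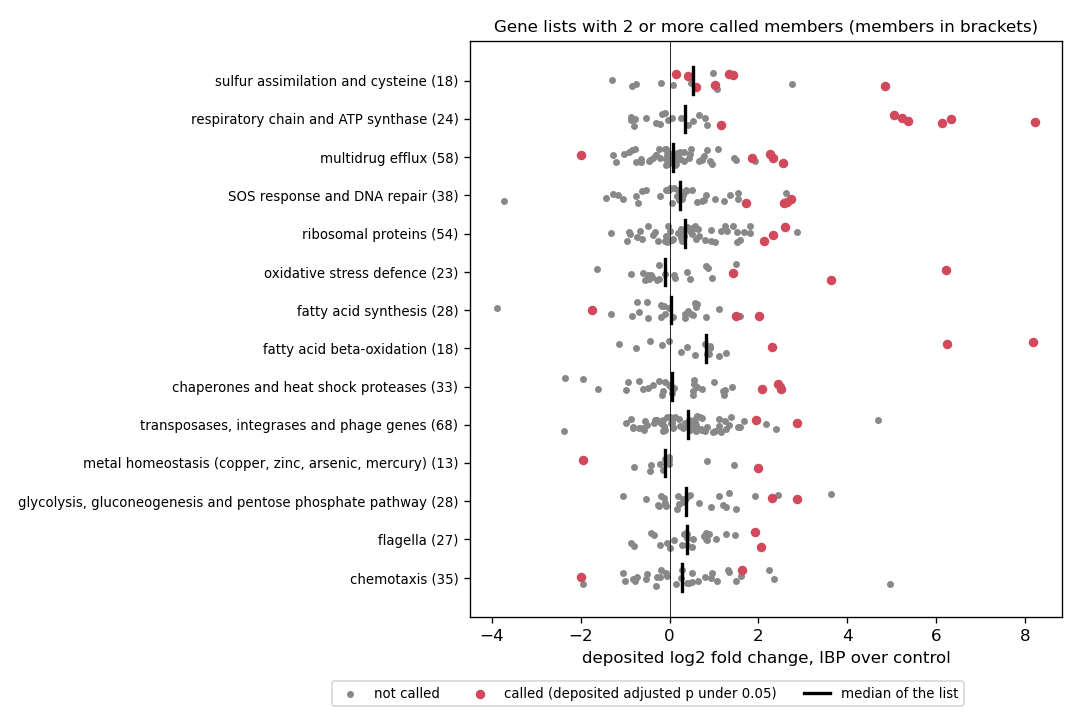
Deposited log2 fold change (horizontal axis, IBP over control) of each member of the gene lists with 2 or more calls; red points are called in the authors' deposited table, grey points are not, and the black bar is the list's median. The 6 nqr genes, fadI, fadJ and katG_1 all lie above 5, to the right of every other member plotted.

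No member was called in the lists of iron uptake (25 genes), envelope stress (27), thioredoxin, glutaredoxin and glutathione (26), nitrogen uptake (9), phosphate uptake (10), secretion (17), osmolytes and sodium homeostasis (21), c-di-GMP signalling (9), polysaccharide hydrolases (12), cell division and peptidoglycan (56) or RNA polymerase and translation factors (30). Deposited log2 fold changes ran from -4.01 to 3.08 in iron uptake and from -3.82 to 1.20 in cell division. The c-di-GMP list had a median of 0.84, at percentile 98.0, and cell division a median of -0.08, at percentile 3.5.

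Outside the lists, the largest listed rise is that of gmk, for guanylate kinase, at 1229-fold in the authors' deposited table from 46.1 ± 7.52 TPM. The gene smpB, whose product binds the ribosome-rescue RNA, was at 215 ± 47.0 TPM and nadB, for an enzyme of NAD synthesis, at 202 ± 59.6 TPM, with folds of 75.1 and 73.8 in the authors' deposited table, both as rows of constant 1. Among genes listed as lower, lpxB, for lipid A disaccharide synthase, was at 1665 ± 192 TPM in the controls and has a fold of 0.117 in the authors' deposited table. It is adjacent to lpxA, listed above. The transport gene yajR (38.1 ± 6.49 TPM), the membrane protein gene yhaH (30.3 ± 1.37 TPM) and the magnesium transporter gene mgtE_1 (904 ± 202 TPM) have folds of 0.165, 0.196 and 0.202 in the authors' deposited table. Neighbours of yhaH with hypothetical products, at loci 03725 and 03727, are listed at 0.0945 and 0.0714 in the authors' deposited table. Histidine ammonia-lyase (hutH, 79.8 ± 1.97 TPM), the tRNA deaminase gene tadA_2 (280 ± 17.2 TPM), the DNA base-flipping protein gene at locus 00069 (95.1 ± 10.4 TPM) and ybaK (213 ± 14.6 TPM) are listed at 0.207, 0.223, 0.226 and 0.232 in the authors' deposited table.

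Between 0.05 and 0.83, the deposited p-values do not follow the fold changes. Over the 3850 mRNA rows with p from 0.05 to 0.83, the p-value rose with the locus number in 3830 of 3849 neighbouring pairs (99.5%), with a Spearman rho across genes that rounds to 1. Across the same genes, rho between p and the size of the log2 fold change was -0.04. Genes are not independent replicates, so these are descriptions of the table. Of 256 rows with a log2 fold change beyond 2 in size, 163 are not called. One of them, rcp1_3, a response regulator gene named after its value was seen, is listed at 55.8-fold with a p of 0.696 in the authors' deposited table. A call that is missing there is therefore not evidence that a gene's level stayed the same.

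**Figure D3:**
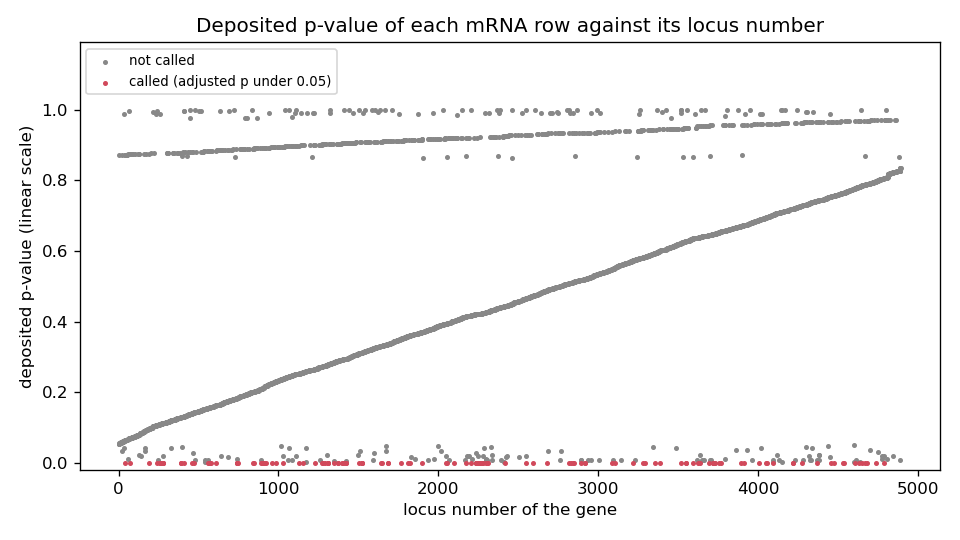
Deposited p-value (vertical axis, linear) against locus number (horizontal axis) of each mRNA row; red points are called rows. The grey rows between 0.05 and 0.83 form one rising line.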

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

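The limits of the table come before any setting. The treated columns restate the controls, so the planned limma, camera and fry fits were not run, nor were their alternatives (pseudocounts of 0.1 and 5, quantile normalization, fits without trend, and leaving out samples from the group comparison). Count-based alternatives had no counts to start from. No paired analysis was possible because each treated column is the control column of the same number times the fold change, so that within a replicate number the only spread left is that of the column constants and rounding. At an adjusted p under 0.01, the authors' deposited table has 89 calls in place of 149, and 89 in place of 146 with at least a 2-fold change. With 10 or more in at least 3 of the 6 columns, 130 and 128 calls are left. These columns include the treated ones, so a gene listed as higher can pass through its fold alone. An example is nqrE, at 7.91 TPM in the controls with a fold of 41.1 in the authors' deposited table. The filter therefore does not show whether the calls depend on low control levels. Chosen after seeing the data, Benjamini-Hochberg adjustment of the deposited p-values gave 150 calls, 149 of them shared, although 1044 rows differed by more than 0.001 in adjusted p. Leaving out the rows of constant 1 and the 2 rows that match neither product left 124 calls, 122 of them at 2-fold or more. The number of product rows was 4790 at a tolerance of 1e-12 and 4791 at 0.001. Calls summed over the gene lists went from 52 to 46 with members taken by product text only, to 35 without the rows of constant 1 and the 2 rows that match neither product, and to 35 at an adjusted p under 0.01, a threshold added for the lists after seeing the data. At 0.01, sulfate assimilation has 2 calls in place of 7, chaperones 1 in place of 3 and DNA repair 2 in place of 4. Multidrug efflux has 3 in place of 5, metal homeostasis 1 in place of 2 and flagella 1 in place of 2. The tricarboxylic acid cycle has 0 in place of 1 and oxidative stress 2 in place of 3. The respiratory chain list has 6 in place of 7 and fatty acid synthesis 2 in place of 3. The median control TPM of ribosomal protein genes ran from 12.8 to 15.3 when each control replicate was left out. Depth is unknown, since TPM keeps none.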

Other observations

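All tests in this part except the shift of names against values were chosen after the result was seen. Called genes lie side by side in the order of locus numbers. Of the 145 called mRNA genes, 53 have a neighbour called in the same direction, against a median of 4 and at most 20 in 10000 random placements of the same calls. Random placement takes calls as free of row order, and the deposited p-values follow that order in part (the second pattern below), so this count cannot be read as shared regulation of neighbours. Besides the nqr genes, loci 02245 to 02257 hold 10 called genes, all listed as higher, with log2 fold changes from 1.66 to 8.17, hsp90, radA, abcA, fadI and fadJ among them. Loci 00273 to 00278 hold 4 called genes listed as higher, among them recF and recN of DNA repair and cysI of sulfite reduction. Loci 03721 to 03729 hold 6 called genes listed as lower, with log2 fold changes from -3.81 to -2.35, including truC, for a tRNA pseudouridine synthase, and yhaH.

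Of the 183 sRNA candidates, 4 are called in the authors' deposited table: sRNA0135 and sRNA0080, with log2 fold changes of 3.17 and 2.63, and sRNA0309 and sRNA0187, with -2.23 and -2.53. Some of the most abundant rows are sRNA candidates. Control levels were 48277 ± 25391 TPM (SD, n = 3) for sRNA0204 and 27299 ± 4769 TPM for sRNA0286, and neither is called.

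The first pattern is the match of treated columns to control columns times fold change, seen in 98.95% of rows. One scaling factor per library is argued against, because it would leave each treated ratio its own spread over genes, and after the control ratio was taken out the SD was 0.00818 against 0.308 between controls, over all 2857 genes at 10 or more in the 6 columns. Paired libraries, or an adjustment for replicate made before rounding, are argued against as well: 99.09% of rows under 10 control TPM match the product of control values already rounded to 2 decimals. A candidate explanation is that the treated columns were computed from the control columns and the fold change, and the table does not show when or why. The fold changes themselves could come from treated libraries not analysed here, which these values can neither show nor exclude.

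The second pattern is the rise of the deposited p-value with locus number, in 99.51% of neighbouring rows between 0.05 and 0.83. A change of the response along the chromosome is argued against, since the size of the log2 fold change followed locus number with a rho of only -0.0392 in the same rows. A candidate explanation is that p-values were filled or sorted in row order apart from the other columns. Rows under 0.001 had rising locus numbers in 68.3% of neighbours, so whether the called p-values belong to their genes stays open.

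The third pattern is the low level of ribosomal protein genes in the controls, which in a growing bacterium are usually among the most abundant. Their median stood at percentile 40.7 of the annotated genes, with 21 of 54 under 10 TPM, and neighbouring genes correlated in level with an r of only 0.247 across 4555 pairs. A few rows taking most of the total is argued against, since a common factor leaves the percentile of 40.7 as it is. A shift of names against values by a fixed number of rows, up to 50 either way, is argued against too: the highest median percentile at any other offset was 69.1. Other mismatches between names and values, and a true low level, were not tested, and gene names in the table are open to doubt to that extent. Why rpsO, a member of this list, has the same control mean and SD as mcpU was not tested either.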
